A study of Mus musculus with 2 samples.

How the data were processed

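H3K27me3 ChIP-seq was done on hearts of B6NCrl mouse embryos at embryonic day 13.5, with both sexes pooled, in 2 biological replicates that form 1 group. The starting point was 4 peak lists on mm10. Per the text files deposited beside the lists, replicate 1 was called against 2 control files and replicate 2, which joins 2 technical replicates, against 1 control file. Per the same files, the pooled list was made from both replicates' filtered alignments, and the replicated list was derived from the pooled list and both replicates' lists. The aligner, the peak caller and its threshold are not given in the sources used here. A list in which replicates differ in controls or depth also differs in the number of peaks that pass a threshold. Counts of peaks in whole lists are therefore compared here together with ranks, equal list lengths and chance overlap. Counts of peaks per chromosome and numbers of domains are given as they stand, without such a check. Separate animals stand behind the biological replicates only as far as that label says. The labels do not state how many embryos each pool held.

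The deposited files give each peak a fold enrichment over control (a ratio), which was read as such from the fixed columns of the peak format. They also give the authors' −log10 p and −log10 q per peak. These scores are the authors' own and were used to describe, rank or filter peaks within 1 list. In the deposited lists the −log10 p was never below 2.00. No list holds read counts, so the depth per sample is unknown and no interval for depth is given. Beside shares of peaks and genes, the spread of the 2 replicates' own lists is given. It is not the error of a share from the replicated list, which is drawn from pooled peaks and can lie outside both replicates. Cardiac transcription factors, for example, were 52.4% marked in the replicated list, 47.6% in replicate 1 and 42.9% in replicate 2.

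The reference was GRCm38 (mm10) with GENCODE M21. The match of builds was checked from the coordinates: 0 peaks reached past the end of a chromosome in any list. There were 0 peaks on chromosomes Y and M, and 1 peak on an unplaced sequence in the pooled list and in that of replicate 1, which was left out of values per chromosome and per gene. Genes were the 21755 protein-coding genes on chromosomes 1 to 19 and X. A promoter was the 2000 bp centred on the gene's annotated 5' end, and it was called marked when peaks covered at least 500 bp. The CpG ratio was the observed over expected number of CpG over 500 bp on each side of the 5' end. Annotation classes were assigned per base pair in the order promoter, exon, intron, intergenic.

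Overlaps were computed with bedtools 2.31.1 and coverage with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. A peak counted as shared when at least 50% of its own length lay in 1 peak of the other list. For pooled peaks against the replicates, 50% of the length of either peak was enough. Chance values came from 100 seeded shuffles of the peaks within their chromosomes, outside unsequenced gaps. Domains were replicated peaks merged across gaps of up to 3 kb. Each of 19 gene lists was tested against all other protein-coding genes with a two-sided Fisher's exact test in scipy 1.17.1, adjusted over the 19 lists by the Benjamini-Hochberg method. These tests treat genes as independent, although neighbouring genes can share a domain, and they describe this tissue and not a difference between groups. All symbols of the lists were found in the annotation. Anterior and posterior HOX genes were compared with a permutation test of 100000 resamples. Figures were drawn with matplotlib 3.10.9.

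The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the 10 longest domains with their genes, the 10 promoters of highest fold (1 per domain), and in each list up to 4 marked members with the most base pairs covered within 5 kb of the 5' end and up to 3 unmarked members with the fewest. It also names all members where 5 or fewer are marked or unmarked, and the Xist region, Cdkn2a, Hoxd13 and Nkx2-5 in any case.

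The procedure was tested on simulated data. Over 100 runs with peaks placed at 19517 real promoters, 0 promoters were called wrongly for the comparison of marked promoters. A simulated list of 30 genes at 50% against a background of 18% fell below an exact p of 0.05 in 92 of 100 runs, and a list at the background share in 2 of 100. For the replicate overlap, a simulated share of 60% over 20000 peaks was recovered as 60%. Simulated promoters were covered well past 500 bp or not at all, and simulated overlaps lay clear of 50%. The settings thus fixed the correct calls, which check the computation only. Simulated lists were random genes, so they do not cover neighbouring genes that share a domain.

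Alternatives covered the authors' threshold (−log10 q of at least 2, −log10 p of at least 5), the overlap criterion, equal list lengths, the ranking score, the covered length (1 and 1000 bp), the promoter window (2.5 kb on each side with 25% covered), any annotated transcript start, the CpG threshold (0.5 and 0.75), a background of CpG-rich promoters, 1 gene per cluster within 100 kb, the merge gap (1 and 10 kb), the pooled list and each replicate alone. Leaving out replicate 1 means that the list of replicate 2 alone was used, and the reverse.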

Results

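H3K27me3, the trimethylation of lysine 27 of histone H3 that Polycomb repressive complex 2 lays down at silenced developmental genes, was mapped by chromatin immunoprecipitation and sequencing in the hearts of mouse embryos (strain B6NCrl) at embryonic day 13.5. Embryos of both sexes were pooled, per the labels. The series holds 1 group with 2 biological replicates, so the only comparison between samples is that of replicate 1 with replicate 2. The question that the data address is where in the genome of the midgestation heart the mark lies. Each replicate has its own list of peaks, and a pooled and a replicated list were made from both. Read depth is unknown, because the lists hold no read counts. All positions are on mm10, and genes carry their GENCODE identifiers.

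The mark covered a small part of the genome and lay far more often at promoters than their length would give. The replicated list held 72839 peaks with a median width of 619 bp, which covered 79.7 Mb or 3.11% of the sequenced genome. Promoters, taken as 1 kb on each side of the 5' end of a protein-coding gene, made up 7.72% of the covered base pairs and 1.60% of the genome, a 4.83-fold excess. Exons made up 7.35% against 3.37%, a 2.18-fold excess. Introns made up 37.8% against 36.2%, which lay within the range of 100 shuffles of the peaks, and intergenic sequence made up 47.1% against 58.9%. None of the 100 shuffles put more than 1.84% of the covered base pairs in promoters or less than 56.8% in intergenic sequence. Covered base pairs came to 75.4 ± 22.8 Mb (SD, n = 2) over the replicates.

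Of 21755 protein-coding genes, 3950 or 18.2% had a marked promoter, with at least 500 of its 2000 bp covered by replicated peaks. The share was 18.6% with the peaks of replicate 1 alone and 15.3% with those of replicate 2, or 17.0% ± 2.38 (SD, n = 2). Marking was most frequent at promoters of intermediate CpG content. With an observed over expected CpG ratio between 0.4 and 0.6, 1035 of 3060 promoters were marked (33.8%; replicates 31.7% ± 3.05, SD, n = 2). At ratios of 0.6 or more 1854 of 10075 were marked (18.4%), and below 0.4 the count was 1061 of 8620 (12.3%). Promoters at 0.6 or more did not differ from all others in Fisher's exact test (odds ratio 1.03, two-sided p = 0.388). That comparison passed the threshold with replicate 2 alone (odds ratio 1.14, exact p = 0.000379) and with 1000 bp covered (1.09, exact p = 0.0228). With replicate 1 alone the odds ratio was 0.969 (exact p = 0.373), and other CpG thresholds gave 1.40 at a ratio of 0.5 (exact p = 4.68e-21) and 0.674 at 0.75 (exact p = 6.62e-22).

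Most promoters of HOX genes and of neural, endoderm and other mesoderm transcription factors carried the mark in the heart. All 39 HOX cluster genes and all 52 neural transcription factors had marked promoters. Among them were Neurog1, Neurod2, Olig2 and Nkx6-1, which specify neurons and glia, each with all 10000 bp around its 5' end covered by replicated peaks. Of 17 endoderm transcription factors 15 were marked, including Foxa1, Foxa2, Cdx2 and Onecut1. Hnf4a and Sox15 were the exceptions, and Hnf4a had 715 bp covered in replicate 1 and 0 bp in replicate 2. Of 27 transcription factors of other mesoderm 24 were marked, among them Pitx1, Six2, Evx1 and T, the gene for brachyury. Tbx6, Meox1 and Osr1 were not, although Osr1 had 457 bp covered, just under the minimum. Hnf4a and Osr1 were marked at another annotated transcript start. Each of these groups exceeded the 18% of all other genes in Fisher's exact test, with adjusted p = 6.87e-29 for HOX genes, 2.13e-38 for neural, 2.23e-09 for endoderm and 9.77e-15 for other mesoderm factors. HOX genes lie in few clusters, and with 1 gene per cluster 4 of 4 were marked (adjusted exact p = 0.00223). The neural, endoderm and other mesoderm lists also passed the threshold in that setting. Over the replicates the neural list was at 99.0% ± 1.36 (SD, n = 2), and the endoderm list at 88.2% ± 8.32.

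Secreted ligands of the WNT, hedgehog, FGF and BMP families showed the same pattern, with 34 of 38 marked (88.2% ± 1.86 over the replicates, SD, n = 2; adjusted p = 9.27e-21, Fisher's exact test). Wnt7a, Wnt10a, Shh and Fgf3 had all 10000 bp around their 5' ends covered. The 4 unmarked ligands were Fgf10, Fgf20, Bmp5 and Wnt5a. Wnt5a had 46 bp of its promoter covered, and the other 3 had 0 bp. Wnt5a, Fgf10 and Fgf20 were marked at another annotated transcript start, which left Bmp5.

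**Figure D1:**
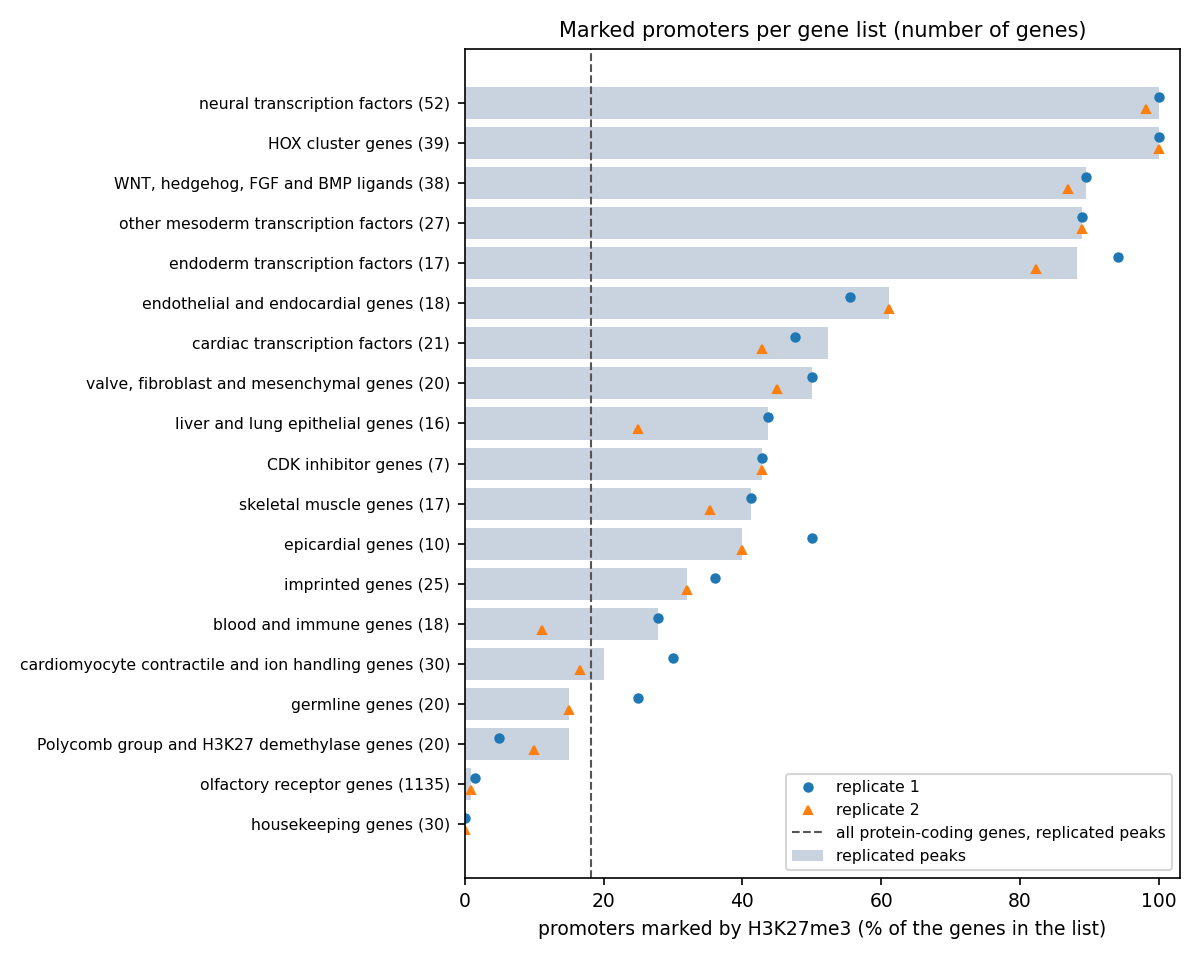
Share of genes with an H3K27me3-marked promoter (x axis, percent) in each of the 19 gene lists (y axis, number of genes in brackets). Bars give the replicated peaks, circles replicate 1 alone, triangles replicate 2 alone, and the dashed line marks the 18.2% of all protein-coding genes. HOX and neural regulators stand at 100%, and housekeeping genes at 0%.

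The 3 longest merged domains of the mark lay over the HoxC, HoxA and HoxB clusters. Replicated peaks merged across gaps of up to 3 kb gave 22977 domains with a median length of 1746 bp, of which 2844 were 10 kb or longer. The number of domains was 42618 with replicate 1 alone, 29888 with replicate 2 alone and 40995 in the pooled list. It was 35105 at a gap of up to 1 kb and 13973 at up to 10 kb. The longest covered the HoxC cluster over 281.6 kb of chromosome 15 (102876549 to 103158140), with 95.3% of its base pairs inside peaks. HoxA followed with 277.0 kb on chromosome 6 (52056216 to 52333199), which also took in Evx1, and HoxB with 239.8 kb on chromosome 11 (96227031 to 96466853), reaching Skap1. Hoxd13, a regulator of the distal limb, lay in a HoxD domain of 131.2 kb on chromosome 2, which was not among the 10 longest. Other long domains held Cdh22 (209.1 kb, chromosome 2), Chrna4, Kcnq2 and Eef1a2 (165.2 kb, chromosome 2), Ephb2, C1qa, C1qb, C1qc and Epha8 (163.6 kb, chromosome 4), Sipa1l3 (158.2 kb, chromosome 7) and Rhcg (152.5 kb, chromosome 7). A pair of the 10 longest were on chromosome X. The order depended on the list, as the longest domain was that of HoxB with replicate 2 alone (300.0 kb) and in the pooled list (381.6 kb) and that of HoxA with replicate 1 alone (283.5 kb). At a gap of up to 10 kb the longest domain reached 820.7 kb, on chromosome 9, and only 1 of the 10 longest domains was still among the 10 longest.

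Anterior HOX genes, used near the head, and posterior ones, used towards the tail, were marked alike in full. All 15 promoters of paralog groups 1 to 5 and all 16 of groups 9 to 13 were marked. Replicated peaks covered 99.6% ± 0.75 (SD over genes, n = 15) of the 2.5 kb on each side of the anterior 5' ends and 98.9% ± 1.71 (SD over genes, n = 16) of the posterior ones. The difference of 0.783 percentage points had p = 0.12 in a two-sided permutation test. Both measures were close to their ceiling, so a difference in the strength of the mark is not excluded.

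**Figure D2:**
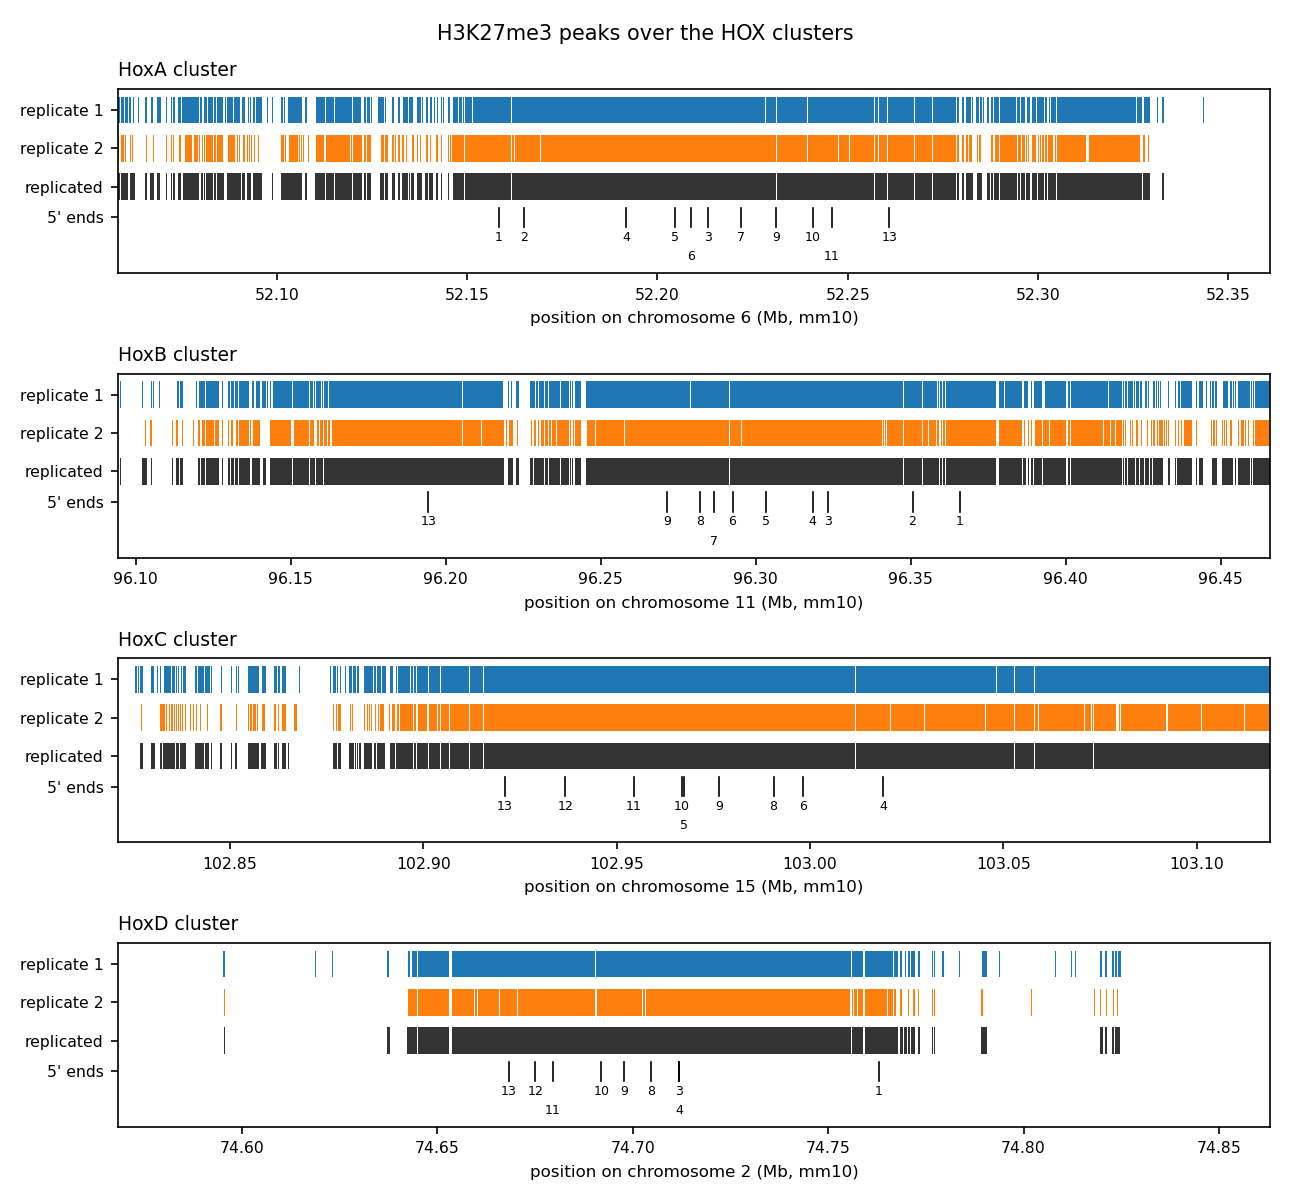
H3K27me3 peaks over the HoxA, HoxB, HoxC and HoxD clusters. The x axes give the position on mm10 in Mb, rows of blocks give the peaks of replicate 1, replicate 2 and the replicated list, and numbered ticks give the 5' ends of the HOX genes by paralog group. All 39 HOX promoters lie inside the blocks of replicated peaks, and in the drawn HoxC window these cover 84.5% of the sequence.

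Promoters were ranked by the fold enrichment that the authors gave each peak, used here only to rank peaks within the replicated list. The 10 promoters named here belonged to genes of different kinds, among them a receptor gene, channel genes and developmental regulators. Whether any class of gene was over-represented at the top of the ranking was not tested. Adra2c, an adrenergic receptor gene, and Dio3, which encodes a deiodinase that inactivates thyroid hormone, stood first with a fold of 15.2. Neurog3, the regulator of pancreatic endocrine cells, had the same rounded fold of 15.2. Galnt9, Wnt3a, Helt, Kcnc1, Kcnk12, Zdhhc22 and Bhlhe23 followed, down to 13.9. Each of these 10 promoters was covered over its full 2000 bp in both replicates.

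The transcription factors of the heart itself were divided. Of 21 cardiac transcription factors 11 were marked (52.4%; replicates 45.2% ± 3.37, SD, n = 2), more often than other genes (odds ratio 4.97, adjusted p = 0.000965, Fisher's exact test). Irx3, Irx4, Tbx1 and Tbx2, which act in parts of the heart or its outflow tract, were covered over 9593 to 9752 bp of the 10000 bp around their 5' ends. Nkx2-5, the homeobox factor of the cardiac lineage, lay on chromosome 17 at 26845009 in a domain of 24.6 kb, and 1940 of its 2000 promoter bp were covered, with 1750 bp in replicate 1 and 1282 bp in replicate 2. Gata4, Gata5 and Gata6 had no replicated peak within 5 kb of their 5' ends and were not marked at any other annotated transcript start.

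Genes of the contractile apparatus and of ion handling in cardiomyocytes did not differ from other genes past the threshold, with 6 of 30 marked (20.0%, odds ratio 1.13, adjusted p = 0.908, Fisher's exact test). Over the replicates the share was 23.3% ± 9.43 (SD, n = 2). The count was 11 of 30 (36.7%) in the pooled list (odds ratio 2.28, adjusted exact p = 0.0513) and with 1 bp covered (adjusted exact p = 0.112), and 5 of 30 with the window of 2.5 kb on each side (odds ratio 0.834). The marked members included Myh7, Myl2 and Myl3, which encode a myosin heavy chain and myosin light chains of the ventricle, and Scn5a, the cardiac sodium channel. Peaks over Myh7, Myl2 and Myl3 had folds of 3.52 to 3.74, and 1029 to 1748 bp of their promoters were covered. For Myl3 the 5' end used, 110741861 on chromosome 9, was the outermost annotated start of a gene that ends at 110769798. The domain over that start was 6.25 kb long, and other starts of Myl3 were not examined separately. The call therefore does not show that the start used in the ventricle was marked. In the single replicates Myh7 had 653 bp covered in replicate 1 and 393 bp in replicate 2, which is below the minimum. Myh6, Myl4 and Actc1, encoding sarcomere proteins of the embryonic or atrial heart, had 0 bp of replicated peaks within 5 kb.

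Endothelial and mesenchymal genes, from the other cell types of the heart, were marked more often than other genes. Of 18 endothelial and endocardial genes 11 were marked (61.1%; replicates 58.3% ± 3.93, SD, n = 2; adjusted p = 0.00017, Fisher's exact test). These included the transcription factors Sox7 and Sox17, the VEGF receptor Flt1 and the endocardial factor Nfatc1, whereas Pecam1, Cdh5 and Tek had no replicated peak within 5 kb. Of 20 valve, fibroblast and mesenchymal genes 10 were marked (adjusted exact p = 0.00253). The mark covered Msx1, Msx2, Twist1 and the smooth muscle myosin gene Myh11, and spared Postn, Col1a2 and Col3a1, which encode matrix proteins. Of 10 epicardial genes 4 were marked, namely Wt1, Tcf21, Aldh1a2 and Lrrn4, which missed the threshold (adjusted p = 0.132, Fisher's exact test) and passed it with replicate 1 alone (adjusted exact p = 0.0385), in the pooled list (0.0118), with 1 bp covered (0.00415), with the wider window (0.0494) and with any transcript start (0.0161). Taken as 1 set, which was done after the values were seen, the genes of these 3 lists were marked more often than contractile genes, at 25 of 48 against 6 of 30 in the replicated list (two-sided p = 0.00831, Fisher's exact test). The difference missed the threshold with replicate 1 alone, at 25 of 48 against 9 of 30 (exact p = 0.0647), and in the pooled list, at 27 of 48 against 11 of 30 (exact p = 0.108). Gene class was not adjusted for, although the larger set includes transcription factors and the contractile list does not.

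Genes of skeletal muscle, liver, lung and blood were divided. Of 17 skeletal muscle genes 7 were marked (adjusted p = 0.0364, Fisher's exact test), with Pax7, Pax3, Lbx1 and Myod1 covered over 9750 to 10000 bp and Myf5, Myf6 and Myog over 0 bp. This call ended with replicate 2 alone (adjusted exact p = 0.0595), with 1 bp covered (0.112) and with a window of 2.5 kb on each side (0.0503). Of 16 liver and lung epithelial genes 7 were marked (adjusted exact p = 0.0276), among them Cdh1, Epcam, Krt8 and Sftpc, but not Alb, Afp or Apoa2. Their share was 43.8% with replicate 1 alone and 25% with replicate 2 alone, where the call ended (adjusted exact p = 0.367), as it did with 1 or 1000 bp covered, the wider window, any transcript start and the CpG-rich background. Of 18 blood and immune genes 5 were marked, namely Tal1, Hba-x, Cd3e, Cd19 and Klf1 (adjusted exact p = 0.418). With replicate 2 alone 2 of the 18 were marked (11.1%, odds ratio 0.693), where Cd3e, Cd19 and Klf1 had 428, 481 and 265 bp covered, and at 1000 bp covered 3 were. The beta-globin genes Hbb-bt, Hbb-bs and Hbb-y had 0 bp within 5 kb.

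No housekeeping promoter was marked, with 0 of 30 in the replicated list and in either replicate (adjusted p = 0.00699, Fisher's exact test). With 1 bp covered or the window of 2.5 kb on each side 1 of 30 was. Actb, Gapdh and Hprt had 0 bp within 5 kb. Olfactory receptor genes were also nearly free of it, with 10 of 1135 marked (0.881%; replicates 1.15% ± 0.374, SD, n = 2; odds ratio 0.0376, adjusted exact p = 2.83e-83). The count was 16 with replicate 1 alone, 20 in the pooled list and 22 with 1 bp covered. With 1 gene per cluster 2 of 86 were marked (adjusted exact p = 2.1e-05). The marked receptors included Olfr94, Olfr95, Olfr222 and Olfr1377. Of 20 germline genes 3 were marked, namely Smc1b, Tdrd1 and Dmc1, while Dazl, Ddx4 and Sycp1 were not (adjusted exact p = 1). With replicate 1 alone, in the pooled list or with any transcript start 5 of 20 were marked, which turned the direction (odds ratios of 1.21 to 1.46).

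Imprinted genes, Polycomb genes and CDK inhibitor genes did not pass the threshold. Of 25 imprinted genes 8 were marked (adjusted exact p = 0.149), including Grb10, Dlk1, Ascl2 and Phlda2 and leaving out Ins2, Rtl1 and Peg3. The adjusted exact p was 0.0499 with replicate 1 alone, 0.0268 with 1000 bp covered and 0.0336 with 1 gene per cluster. Of 20 Polycomb group and H3K27 demethylase genes 3 were marked, the complex members Cbx2, Cbx4 and Phf19, with 611 to 895 bp covered, and Ezh2, Eed and Suz12, the core of the complex that writes the mark, had 0 bp (adjusted exact p = 1). The count was 1 of 20 with replicate 1 alone, 2 with replicate 2 alone and 0 with 1000 bp covered, and Cbx4 had 463 and 443 bp in the replicates, below the minimum in both. It was 6 of 20 with 1 bp covered or any transcript start and 5 with the wider window, which turned the direction (odds ratios of 1.39 to 1.56). Cdkn2a and Cdkn2b, inhibitors of the cell cycle at 1 locus on chromosome 4, shared a domain of 51.0 kb and had 2000 and 1382 promoter bp covered. Cdkn1a was marked with 544 bp, and Cdkn1b, Cdkn1c, Cdkn2c and Cdkn2d were not, so 3 of 7 were marked (adjusted p = 0.149, Fisher's exact test). At another annotated transcript start Cdkn1c was marked too.

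The replicates shared their strong peaks more often than their weak ones. Replicate 1 had 160125 peaks over 91.5 Mb and replicate 2 had 107381 over 59.3 Mb, a ratio of 1.49 in number and 1.54 in covered length. Of the peaks of replicate 2, 60.3% had at least 50% of their length in a peak of replicate 1, against 3.53% for shuffled peaks. In the other direction the share was 24.1% against 2.28%, and the Jaccard index of covered base pairs was 0.433 against 0.0157. None of the 100 shuffles reached the observed values. In the top 10% of each list by the authors' −log10 p the shares were 95.6% for replicate 2 and 64.2% for replicate 1, and in the bottom 10% they were 44.0% and 10.5%. With 1 bp of overlap as the criterion, 72.5% and 41.1% of peaks overlapped.

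**Figure D3:**
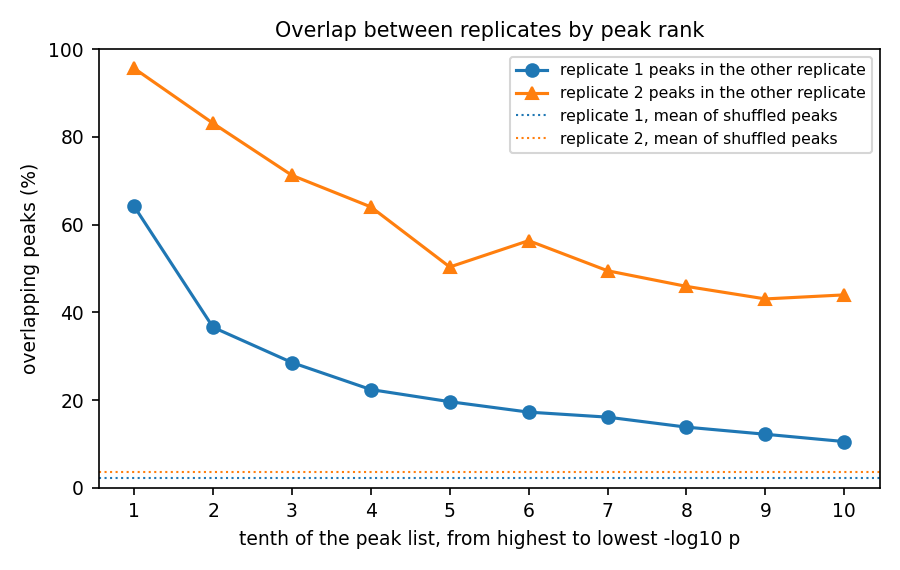
Overlap between the replicates by peak rank. The x axis gives 10 equal parts of each list from highest to lowest −log10 p, the y axis gives the percent of peaks with at least 50% of their length in a peak of the other replicate, and dotted lines give the mean of 100 shuffles. Shares fall from 95.6% to 44.0% for replicate 2 and from 64.2% to 10.5% for replicate 1.

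The replicated list was a part of the pooled list, with 72839 of 172833 pooled peaks (42.1%) at the same positions with the same values. It kept 99.9% of the top 10% of pooled peaks by −log10 p and 5.10% of the bottom 10%. All 54499 pooled peaks that overlapped a peak of each replicate by 50% of either peak's length were in it, and they made up 74.8% of it. At 1 bp of overlap the share was 75.5%, so the other replicated peaks touched no peak in at least 1 replicate.

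Chromosome X departed from the autosomes in how the replicates compared. Replicate 2 had 10102 peaks on X and replicate 1 had 7326, although replicate 2 had fewer on each of the 19 autosomes. The covered length in replicate 2 over that in replicate 1 was 1.33 on X and 0.588 to 0.658 on the autosomes. Per Mb of sequence, X was covered over 19.01 kb in replicate 1, or 0.506 of the autosomal median, and over 25.2 kb in replicate 2, or 1.1 of it. In the replicated list the value was 24.4 kb, 0.768 of the median and rank 12 among 20 chromosomes. Xist, the RNA gene that starts X inactivation, had 0 bp covered in any of the 4 lists between 103460366 and 103483254. A domain of 175.6 kb, merged from 104 peaks with 66.3% of its base pairs inside them, ended short of Xist at 103454040. It held Cdx4, Chic1, Tsx and Gm26992. A domain of 157.7 kb from 99475733 to 99633454, with 71.5% inside 94 peaks, held no 5' end of a protein-coding gene. With 2 replicates, derived with different numbers of control files, the difference on X has no test.

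**Figure D4:**
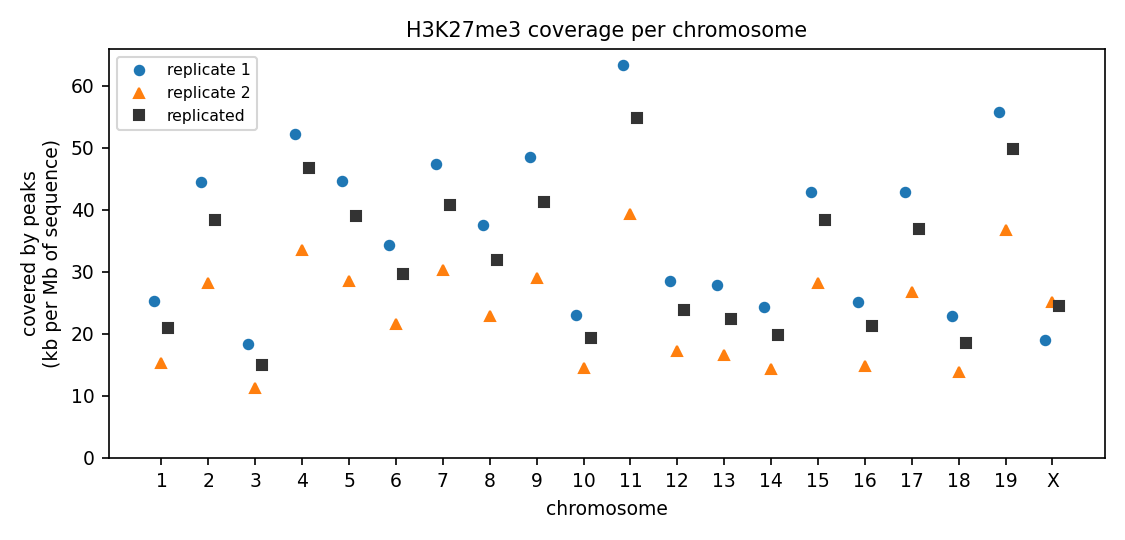
Sequence covered by H3K27me3 peaks on each chromosome (x axis) in kb per Mb of sequence (y axis) for replicate 1 (circles), replicate 2 (triangles) and the replicated list (squares). Replicate 1 lies above replicate 2 on all 19 autosomes and below it on X, at 19.01 against 25.2 kb per Mb.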

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

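The tests of the ratio on X, of equal list lengths and of the marked shares over all promoters were chosen after their results were seen, as were the rule that leaves the test of an inactive X undecided where over 50% of the genes hold no peak, and the values of the cell type comparisons with replicate 1 alone or in the pooled list. The other tests in this part were written down first.

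Chromosome X had more peaks in replicate 2 than in replicate 1. Lower depth or weaker signal of replicate 2 throughout the genome is argued against only by the pattern itself. The covered ratio of 1.33 on X, above the highest autosome at 0.658, restates the pattern and is no separate evidence. A shift of all of X by the different control files stays open. X peaks from the top 10% of replicate 1 had, within the list of replicate 2, a fold above that of autosomal peaks matched on their replicate 1 fold by a median of 0.23 on the log2 scale (95% block bootstrap interval 0.16 to 0.29, 378 peaks), where such a shift needs more than 0.1. More cells with an inactive X in replicate 2 may give that value too, and the test meant to separate it decided nothing: gene bodies subject to inactivation gained 0.125 percentage points more than those of escape genes (permutation p = 0.99), with 19 of 32 subject genes free of peaks in both replicates, so that their median gain of 0 reflects the floor.

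Replicate 1 peaks of the top 10% overlapped single replicate 2 peaks less often than the reverse, at 64.2% against 95.6%. A larger number of peaks in replicate 1 as the whole cause is argued against, since the top 10% of lists of equal length still differed by 24.0 percentage points (71.3% against 95.2%), although that is less than the 31.5 points of the full lists. Splitting of wide replicate 1 peaks into several replicate 2 peaks is a candidate explanation for part of the gap: all replicate 2 peaks together covered 50% or more of 84.7% of these peaks, past the 80% set beforehand, and 48.9% were touched by 2 or more. In the reverse direction these shares were 98.4% and 17.4%, so a gap remained with splitting allowed for. No biological explanation was tested, since the design has 1 group.

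In the replicated list genes of minority heart cell types were marked more often than contractile genes, by 32.1 percentage points (25 of 48 against 6 of 30), but with replicate 1 alone the difference was 22.1 points (exact p = 0.0647) and in the pooled list 19.6 points (exact p = 0.108). Promoter CpG content as the whole cause is argued against in the replicated list, since among promoters with a CpG ratio of at least 0.4 the difference was 47.4 points (21 of 26 against 4 of 12, p = 0.00857, Fisher's exact test), where 20 or more had been set beforehand, although with replicate 1 alone it was 26.9 points and missed the threshold (exact p = 0.139). Below 0.4 it was 7.07 points (4 of 22 against 2 of 18, exact p = 0.673), so the argument covers only ratios of at least 0.4. The set had been joined after its values were seen, and these are the same genes. Both p-values describe these genes and are no independent support. The sets also differ in the class of gene. The minority lists include transcription factors such as Sox7, Wt1 and Msx1, whereas the other list is of contractile and ion handling genes. No test held gene class equal, so the difference cannot be assigned to cell type. A mixture of cell types, each gene being marked in the cells that do not use it, may give the pattern and cannot be told apart from marking within 1 cell type, because lists from whole tissue do not show which cells carry a peak.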

How the results depend on the processing

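Of 308 alternative values, 235 kept their direction and side of the threshold or moved within the limits set, 36 moved, 14 reversed, 11 newly passed and 12 no longer passed. For annotation, coverage of X and marked promoters the limit was the SD of the replicate-alone values, which are themselves among the alternatives. It was wide: X at 0.506 of the autosomal median with replicate 1 alone, against 0.768 in the replicated list, counted as within it. The 235 are thus a lenient count. Of 208 for gene lists, 180 kept both. The CpG-rich background left no olfactory receptor gene, so it gives no value there. Leaving out X, covering peaks by all peaks of the other replicate together, the top 10% at equal lengths and the alternatives for minority against contractile genes were added after seeing the data. Unless the setting itself lowers a count, the cause was not tested. No paired analysis was possible because there is only 1 group. Depth is unknown and limits what the weaker peaks show.

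A −log10 p of at least 5 left 82859 peaks in replicate 1, 54708 in replicate 2 and 91355 pooled. The overlap of replicate 1 and of replicate 2 peaks was 41.1% and 72.5% at 1 bp, 19.9% and 29.7% with reciprocal 50%, 23.6% and 62.2% at −log10 q of at least 2, 29.9% and 54.3% at equal lengths, 28.3% and 62.9% with all other peaks together, and 23.1% and 63.5% without X. The Jaccard index was 0.442 at −log10 q of at least 2 and 0.472 at equal lengths. Ranked by fold, the bottom 10% overlapped at 11.4% and 48.5%, and the top 10% of replicate 2 at 94.8%. At equal lengths the top 10% overlapped at 71.3% and 95.2%. Overlap with both replicates held for 31.5% of pooled peaks at 50% of either peak's length and 32.4% at 1 bp.

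In the pooled list the excess was 3.95 for promoters, 1.958 for exons and 0.840 for intergenic sequence, and leaving out a replicate gave 1.03 to 1.04 for introns. Coverage of X over the autosomal median was 0.506 to 1.1 with 1 replicate left out. Marked promoters were 22.8% at 1 bp covered, 14% at 1000 bp, 21.5% with any transcript start, and 15.3% to 18.6% with 1 replicate left out. The CpG odds ratio was 1.40 at 0.5, 0.674 at 0.75, 1.09 at 1000 bp covered and 0.969 to 1.14 with 1 replicate left out. Domains of 10 kb or more numbered 1731 at a gap of 1 kb, 5027 in the pooled list and 2798 to 4320 with 1 replicate left out, and the longest at a gap of 10 kb was 820.7 kb.

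Skeletal muscle genes lost the call at 41.2% marked with 1 bp covered and with the wide window, and ranged from 35.3% to 41.2% with 1 replicate left out. Liver and lung genes lost it at 43.8% (1 bp; any transcript start), 31.3% (1000 bp), 37.5% (wide window) and 100% of 1 CpG-rich promoter, with 25% to 43.8% on leaving out a replicate. Epicardial genes passed at 70% (1 bp), 50% (wide window), 60% (any transcript start; pooled) and ranged from 40% to 50% with 1 replicate left out. Imprinted genes passed at 32% (1000 bp) and 41.2% (1 per cluster), ranged from 32% to 36%, and turned at 18.2% (CpG-rich). Minority genes exceeded contractile genes by 22.1 to 33.3 percentage points with 1 replicate left out and 19.6 in the pooled list, and at CpG ratios of at least 0.4 by 26.9 to 51.9 with 1 replicate left out. Calls never passed but directions turned for contractile genes at 16.7% (wide window), blood genes at the lower end of 11.1% to 27.8% and germline genes at the upper end of 15% to 25% with 1 replicate left out, germline genes at 15% (1000 bp), 25% (any transcript start; pooled) and 27.3% (CpG-rich), and Polycomb genes at 30% (1 bp; any transcript start) and 25% (wide window).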

Other observations

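Other gene families differed widely in marking. All comparisons in this part were chosen after the data were seen. Genes were grouped by the letters of their symbols, which gave 158 families of 15 or more genes. In Fisher's exact test, adjusted over the 158, 16 were marked more often than other genes and 21 less often. Synaptotagmins (Syt), which trigger vesicle release, had 15 of 17 promoters marked (adjusted exact p = 2.23e-08), with 88.2% in replicate 1 and 76.5% in replicate 2. Inward rectifier potassium channels (Kcnj) had 9 of 15 (adjusted exact p = 0.00364). SOX factors had 13 of 19 and POU factors 10 of 16. Collagens (Col) had 23 of 45 (adjusted exact p = 1.45e-05), keratins (Krt) 25 of 53 (adjusted exact p = 2.82e-05) and regulators of G protein signalling (Rgs) 12 of 23 (adjusted exact p = 0.00244). Keratins differed between the replicates, at 47.2% and 30.2%.

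Families at the other end were of more than one kind. Mitochondrial ribosome genes had 0 of 49 (Mrpl) and 0 of 29 (Mrps) marked, and RNA polymerase subunits (Polr) 0 of 28. Vomeronasal receptors (Vmn) had 0 of 331 (adjusted exact p = 1.37e-27). Beta-defensins (Defb) had 0 of 42, the X-linked Rhox homeobox genes 0 of 34 and zinc finger proteins (Zfp) 26 of 394 (adjusted exact p = 1.41e-09). The Rhox genes stand in contrast to the 39 of 39 HOX genes. Many members of these families lie side by side, so they are not independent. Whether reads can be placed uniquely in families of similar genes, olfactory receptors included, was not examined. A missing peak there does not by itself show a missing mark.

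Bodies of X-linked housekeeping genes subject to inactivation held peaks more often than autosomal housekeeping genes in replicate 2, at 11 of 32 against 0 of 28 (p = 0.000439, Fisher's exact test). In replicate 1 the counts were 7 of 32 and 1 of 28 (exact p = 0.057). Any covered base pair counted, and the lengths of the gene bodies were not matched between the sets. X as a whole also had more peaks in replicate 2, so the counts do not single out genes subject to inactivation. Maged1 had 17.5% of its body covered in replicate 2 and 10.4% in replicate 1, and Huwe1 had 10.2% and 3.19%, the largest gains among the 10 of 32 genes with more cover in replicate 2. Rps4x, with 4.49% in replicate 1 and 0% in replicate 2, Prps1, with 2.6% and 0%, and Ogt, with 4.47% and 3.82%, had less. Among 5 escape genes only Pbdc1 held a peak.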
